A study of Homo sapiens with 119 samples.

How the data were processed

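Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in 119 human coronary artery samples. Per the labels' protocols, pieces of the main coronary arteries were flash frozen after dissection of hearts from transplant recipients and of donor hearts that were not used. Nuclei were isolated on a density gradient by the Omni-ATAC method, transposed, amplified and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Coordinates are on genome build hg38, per the submitters' processing notes. The aligner, the peak caller, the read filters and the counting tool are not given in the sources used here, and neither is the treatment of reads that match several places.

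The deposited table holds raw read counts for 171214 peaks in 119 samples, per the file headers and the whole-number values, and every peak is 501 bp long. The 119 deposited lists of single samples repeat the counts of the table exactly, in 119 of 119 cases, so they hold no peak calls of their own and the planned study of peak recurrence was not run. No genome sequence was used here, so the planned study of transcription factor motifs was not run either. Genes came from the RefSeq annotation of the same assembly, which gave gene starts and ends but neither strand nor exons. The planned promoter window around the transcription start was therefore replaced by a window of 1 kb on either side of both gene ends, called gene end below, and the region upstream of the start by 2 kb on either side of the gene. Intron, exon and untranslated region are thus not given for any peak.

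Each peak was placed as gene end, gene body or intergenic by overlap with protein-coding genes. The gene-linked count of a gene is the sum of reads in all peaks that overlap the gene or its 2 kb flanks, and the gene-end count is the sum over its gene-end peaks alone. Of 19126 autosomal protein-coding genes, 17484 had a linked peak, 15669 had a gene-end peak, and the median gene had 3 linked peaks. A peak linked to several genes counted for each of them, which concerned 6709 peaks, 4.00% of the autosomal set. Every result per sample used the 22 autosomes only. All 342 symbols of the 28 gene lists were matched to the annotation, 1 of them through an older symbol.

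Total reads in peaks per sample ranged from 3256323 to 21405276 with a median of 6461490. At the median depth an autosomal peak held 24 reads. A median of 98.8% of autosomal peaks per sample had at least 10 reads, with a range of 80.4% to 100.0%. Library amplification leaves reads that are not independent molecules, so floors from counts cover counting error only. No pair among the 119 libraries had identical counts, and the correlation of log counts between libraries ran from 0.500 to 0.953 with a median of 0.796.

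The labels name no disease stage, artery, batch or date, so all samples were treated as unassigned, no groups were formed and no groups were compared. Relations across samples were tested on continuous scales instead. The gene lists, scores, tests, covariates, alternatives and the rule for naming genes were chosen before the data were examined. Counts were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1, and log2 counts scaled to library size (log2 CPM) used a prior count of 2. Levels of lists used a pseudocount of 0.5. Genes with low counts were removed by filterByExpr, which left 17452 genes and 167011 autosomal peaks. A list score is the mean over the tested genes of the list of their z-scored log2 CPM.

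The level of each list was its median log2 CPM over genes, set against 10000 random lists of the same size matched on the length of the linked region. Scores of 10 cell type lists were compared in 45 pairs by Pearson r and Spearman rho, each with a two-sided permutation test of 100000 resamples and Benjamini-Hochberg adjustment over the 45 pairs. The r of each pair was also set against the central 95% of r over 1000 pairs of random lists matched on level and size, and was computed again without the 2 samples farthest from the median of the score on the x axis. Gene-linked counts were regressed on each of 3 scores (contractile smooth muscle, macrophage, T and NK cell) with the quasi-likelihood F test of edgeR, with depth and the gene-end share of reads as covariates, both as z scores. Slopes are log2 changes per SD of the score, with a standard error from the F statistic, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Genes of the score list and genes whose linked regions overlap them were left out of the counts.

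For each score, 27 lists were tested with camera in limma, two-sided, with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. The spread of each gene over samples is the edgeR biological coefficient of variation with both covariates in the model. Principal components were taken from log2 CPM of the filtered autosomal peaks, and 45 relations of the leading 3 components with depth, gene-end share and 13 scores were tested by permutation in the same way. The 13 scores were the 10 cell type scores and those of the hepatocyte, neuron and keratinocyte lists, cell types from outside the artery.

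The genes named along a score are the 10 with the largest positive and the 10 with the largest negative change among those past the test, with an average level at or above the median of tested genes and the same sign in the gene-end count. For each list the members with the largest changes past the test are named. For levels the 2 members with the highest median CPM are named, and for variability the 15 genes with the highest coefficient at or above the median level. Genes and samples named outside this rule are marked as chosen after their values were seen. Results of a few genes that meet these rules are not reported here.

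The 28 lists cover contractile and modulated smooth muscle, fibroblast, endothelial, pericyte, macrophage, T and NK, B and plasma, mast, adipocyte, cardiomyocyte, Schwann and erythroid cells. They also cover hepatocyte, neuron and keratinocyte markers, housekeeping genes, extracellular matrix, osteochondrogenic, lipid handling, inflammatory, interferon response, immediate early, hypoxia, oxidative phosphorylation, TGF-beta signalling and MHC class II genes, and genes near coronary artery disease loci.

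Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors, no filter on low counts, gene-end counts, counts per kb of peak, no covariates, the 3 scores in 1 model, an estimated correlation in camera, scores from medians, depth and gene-end share partialled out, other gene-end windows and the 5000 most variable peaks. The following were added after the data were seen. They were the strongest peak per gene, the mean score of the 3 outside cell types as a further covariate, leaving out the 2 samples lowest on the second principal component, and leaving out 17 samples with high counts at 3 genes. Peaks on chromosome X and on unplaced sequence entered no comparison.

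The procedures were tested on simulated counts for the 17452 genes, drawn with the means, dispersions and depths of these samples, with 50 genes changed per effect size. At 0.2 log2 units per SD, 100% of changed genes were recovered on the contractile score, 98% on the macrophage score and 90% on the T and NK cell score. At 0.1 the shares were 86%, 86% and 38%, and at 0.05 they were 28%, 40% and 8%. False calls numbered 7, 9 and 4. Of 200 lists of unchanged genes, camera gave p under 0.05 to 11, 9 and 6. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for counting and plots.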

Results

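Open chromatin was profiled in 119 human coronary artery samples, each with its own number in the labels and taken here as 1 per patient. Coronary arteries carry a medial layer of smooth muscle, an endothelial lining, an outer coat with fibroblasts, fat and nerves, and, in atherosclerosis, macrophages and lymphocytes. The study describes patients at several stages of atherosclerosis, but the labels attach no stage to any sample, so the 119 samples form a single unassigned set. The comparisons below ask which cell type and pathway genes differ in accessibility from artery to artery, and which differ together. Total reads in peaks had a median of 6461490 per sample and ranged from 3256323 to 21405276, a 6.57-fold range. Values are reads in peaks of equal length, scaled to library size (CPM), and coordinates are on hg38.

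Open regions lay mostly away from gene ends, but those at gene ends had higher counts. Of 167709 autosomal peaks, 19167 (11.4%) lay within 1 kb of either end of a protein-coding gene, 73306 (43.7%) within gene bodies and 75236 (44.9%) between genes. Gene-end peaks had a median of 10.6 CPM, against 3.84 CPM in gene bodies and 3.63 CPM between genes. The median sample placed 27.8% of its autosomal reads at gene ends (range 18.3% to 40.7%), 37.5% in gene bodies (34.4% to 40.8%) and 34.4% between genes (24.8% to 42.4%). The gene-end share thus varied 2.22-fold between samples, more than the gene-body share at 1.19-fold, and it served as a measure of signal against background. With windows of 500 bp and 2 kb the median share was 24.9% and 31.4%.

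Immediate early, TGF-beta and hypoxia genes carried high accessibility in these arteries, and so did extracellular matrix and contractile smooth muscle genes when all linked peaks were summed. NR4A1 and IER2, immediate early genes, had medians of 174 and 136 CPM (quartiles 157 to 198 and 120 to 155). Among TGF-beta genes LTBP1, which tethers the latent growth factor to matrix, had 332 CPM and the repressor SKI 270 CPM. LTBP1 sums 68 linked peaks, the strongest at 2.91 times the median intergenic peak. SKI sums 21, the strongest at 16.9 times. The myosin light chain kinase MYLK had 299 CPM (quartiles 266 to 359) and the actin-binding protein SYNPO2 236 CPM, each summed over 46 linked peaks. MYH11, the smooth muscle myosin heavy chain, had a median of 153 CPM and spanned 132 to 217 CPM between quartiles. The highest medians of all lists belonged to TNS1, a focal adhesion protein, and COL4A2, a basement membrane collagen, both near coronary artery disease loci, at 654 and 369 CPM. They sum 65 and 51 linked peaks.

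The median log2 CPM of the immediate early list was 6.51, above all 10000 random lists of matched length. The contractile list had 6.12 (percentile 99.8). TGF-beta genes had 6.21 (percentile 99.99), genes near coronary artery disease loci 6.12 (percentile 100), hypoxia genes 6.01 (percentile 99.9), extracellular matrix genes 5.84 (percentile 98.5), housekeeping genes 5.39 (percentile 97.8) and pericyte genes 5.79 (percentile 96.1). The matrix list was led by COL5A2 and COL5A1 at 185 and 179 CPM, the hypoxia list by NDRG1 at 123 CPM, and the pericyte list by CSPG4 and PDGFRB at 157 and 120 CPM. Several of these ranks depended on summing all linked peaks. With gene-end counts, counts per kb of peak and the strongest peak, the contractile list stood at percentile 18.2, 33.4 and 24.6, the pericyte list at 1.57, 9.78 and 15.6, the coronary artery disease list at 42.6, 50.3 and 55.2 and the matrix list at 55.5, 70.3 and 52.4. The lowest percentile over these settings was 99.7 for immediate early, 97 for housekeeping, 92.3 for TGF-beta and 83.1 for hypoxia genes.

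Other resident and immune cell lists lay in the middle or lower range when all linked peaks were summed. The modulated smooth muscle list, led by LTBP2 (179 CPM), stood at percentile 62.5, the adipocyte list with GPD1 (83.8 CPM) at 51.1, and MHC class II genes with their activator CIITA (158 CPM) at 52.9. Lower came lipid handling with the lysosomal lipase LIPA (193 CPM) at 34.1, macrophage with CSF1R and CD68 (84.5 and 49.9 CPM) at 33.9 and fibroblast with SCARA5 (94 CPM) at 31.5. Then followed interferon response at 19.1, osteochondrogenic with RUNX2 (97.3 CPM) at 17.2, endothelial with ERG and VWF (165 and 95.7 CPM) at 16.2 and inflammatory with RELB (72.7 CPM) at 14.1. Gene-end counts, counts per kb and the strongest peak put the modulated smooth muscle list at 10.9, 19.4 and 7.56, the adipocyte list at 1.03, 2.11 and 5.68, the MHC class II list at 16.6, 19.8 and 19.2 and the fibroblast list at 0.09, 4.88 and 0.47. They put endothelial genes at 2.79, 1.86 and 1.01 and macrophage genes at 8.72, 31.5 and 11.9. Inflammatory genes stood at 34, 8.15 and 15.8 and osteochondrogenic genes at 4.44, 27.5 and 5.92. Oxidative phosphorylation, led by ATP5F1B (73.1 CPM), stood at 76.4 in the sum and at 92.6, 99.7 and 98.3 in these settings.

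Lymphoid, mast, cardiac, glial and outside cell types were lowest when all linked peaks were summed. Other settings changed this order. With counts per kb the Schwann cell list stood at percentile 14.9, above the endothelial list at 1.86. With gene-end counts the fibroblast list, at 0.09, lay below the B and plasma cell list at 1.14. The percentiles that follow are those of the sum. The T and NK cell list, with BCL11B and CD247 at 82 and 63.8 CPM, stood at percentile 2.62, the mast cell list with KIT (23.2 CPM) at 3.81, the B and plasma cell list with PAX5 (75.3 CPM) at 0.49 and the Schwann cell list with PMP22 (87.4 CPM) at 1.51. Cardiomyocyte genes stood at 0.23 although RYR2, a long gene with 46 linked peaks, had 172 CPM. The lists of cells that an artery should lack stood at 3.51 for hepatocyte, led by TF (56 CPM), 0.66 for neuron, led by RBFOX3 (98.8 CPM), and 1.64 for keratinocyte, led by SFN (40.1 CPM). The erythroid list, with EPB42 at 11.5 CPM, stood at 1.79.

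The strongest single peak of each gene separated the lists in another way. Every one of the 15 immediate early genes had a peak over 3 times the median intergenic peak of 3.87 CPM, and the median over these genes was 10.5-fold. All 10 housekeeping genes also passed 3-fold, with a median of 7.35-fold, while 8 of 14 contractile genes did, with a median of 3.40-fold. Of all genes with a linked peak 63.9% passed. Of the markers of infiltrating cells, 3 of 14 macrophage genes and 1 of 13 T and NK cell genes passed, with medians of 2.65-fold and 1.5-fold. No endothelial, neuron or erythroid gene passed 3-fold.

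**Figure D1:**
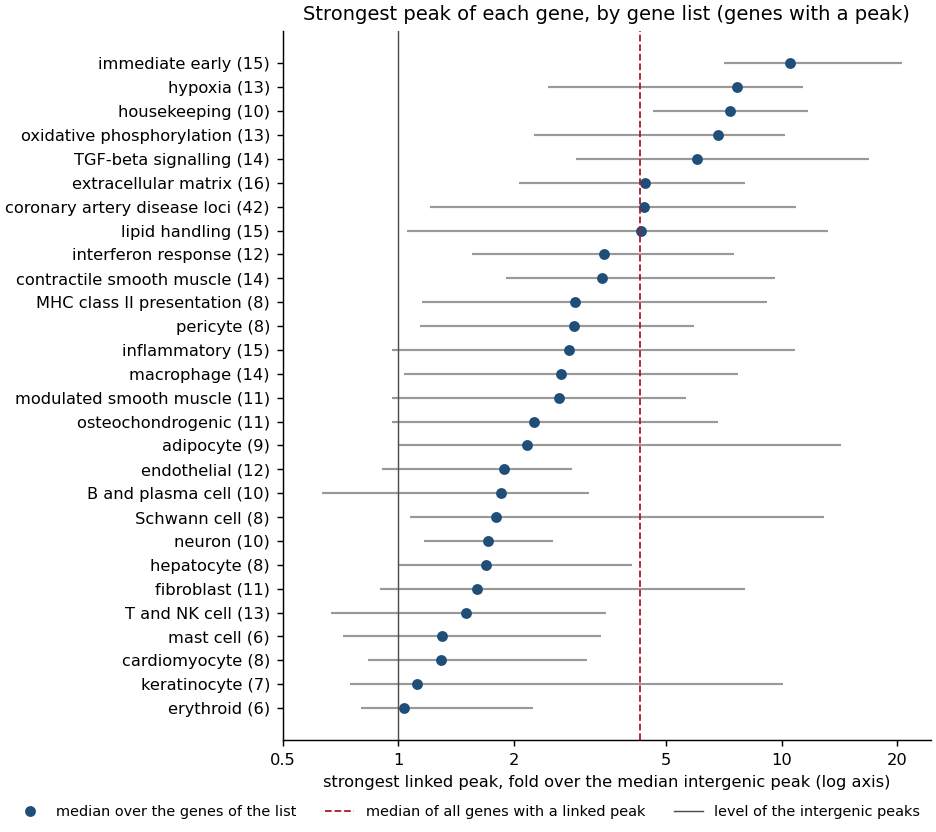
For each gene list, the point is the median over its genes of the strongest linked peak, as fold over the median intergenic peak (log axis), and the line runs from the lowest to the highest gene, with the number of genes that have a peak in brackets. Immediate early genes lie highest at 10.5-fold, all genes with a linked peak have a median of 4.28-fold, and contractile smooth muscle genes lie at 3.40-fold.

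Arteries with more accessible contractile smooth muscle genes had less accessible macrophage and lymphocyte genes. The contractile score, the mean of MYH11, ACTA2, CNN1 and their partners in the contractile apparatus, and the macrophage score, from CD68, CSF1R, the C1Q genes and others, had r = -0.646 (95% interval -0.740 to -0.527) and rho = -0.650 over 119 samples. Without the 2 samples farthest from the median r was -0.665. This r lay below the range of -0.593 to 0.599 that pairs of matched random lists gave. Contractile and T and NK cell scores had r = -0.576 and rho = -0.514, with r = -0.565 without 2 samples, inside the random range of -0.655 to 0.564. Contractile and B and plasma cell scores had r = -0.658 and rho = -0.637, with r = -0.640 without 2 samples, also inside the random range of -0.751 to 0.705.

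Immune cell lists rose and fell together. T and NK cell and B and plasma cell scores had r = 0.932 and rho = 0.889 (r = 0.919 without 2 samples), above the random range of -0.465 to 0.798. Macrophage and T and NK cell scores had r = 0.688 and rho = 0.593 (r = 0.618 without 2 samples), above the range of -0.509 to 0.670. Such r values were not limited to immune lists. Endothelial and T and NK cell scores had r = 0.749 and rho = 0.713 (r = 0.719 without 2 samples), above the range of -0.568 to 0.680. With depth and gene-end share partialled out, that pair had -0.237, while T and NK cell and B and plasma cell scores had 0.831. Contractile and modulated smooth muscle scores had r = 0.621 and rho = 0.595 (r = 0.561 without 2 samples), inside the range of -0.607 to 0.691. Contractile and fibroblast scores were not related (r = -0.0038, permutation p = 0.966, adjusted p = 0.966, rho = -0.046, p = 0.615, adjusted p = 0.629, r = -0.080 without 2 samples).

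Of the 45 pairs computed, 31 had a positive and 7 a negative r past the adjusted threshold, and 12 lay outside the range of their matched random pairs, 11 above and 1 below. With depth and gene-end share partialled out in both, 23 lay outside it, 8 above and 15 below. Each r and rho given as related had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 1.5e-05. Depth and gene-end share of reads moved many pairs. With both partialled out, 18 pairs were positive and 19 negative, and endothelial and cardiomyocyte scores went from r = 0.878 to a partial r of -0.058 (adjusted p = 0.570). The opposition of contractile and macrophage scores had a partial r of -0.618 (95% interval -0.718 to -0.491), that of contractile and T and NK cell scores -0.697, that of contractile and B and plasma cell scores -0.759, and the partial r of macrophage and T and NK cell scores was 0.747, each with an adjusted p of 1.96e-05. The partial r of matched random pairs ranged from -0.452 to 0.430, -0.491 to 0.431, -0.456 to 0.38 and -0.296 to 0.468, so all 4 lay outside.

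**Figure D2:**
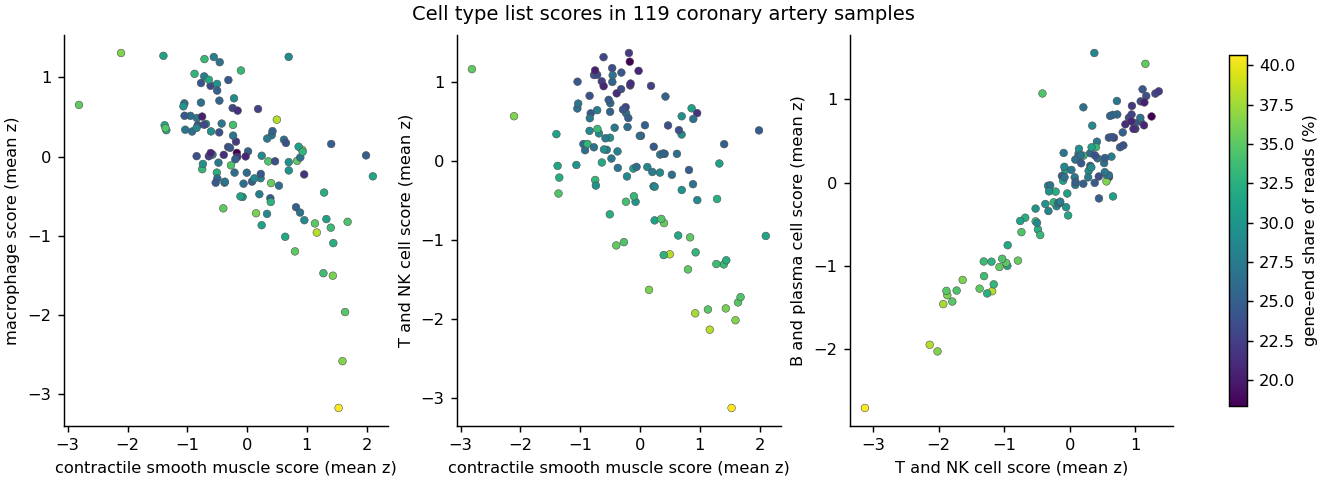
Each point is a sample out of 119, with scores as mean z values on both axes and colour for the gene-end share of reads in percent. From left to right the panels show contractile smooth muscle against macrophage (r = -0.646), contractile smooth muscle against T and NK cell (r = -0.576) and T and NK cell against B and plasma cell (r = 0.932).

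Along the contractile smooth muscle score, other muscle, matrix and mural cell genes rose and leukocyte genes fell. TINAGL1, a matrix protein of basement membranes (chromosome 1, 31576515 to 31587686), rose by 0.58 log2 units per SD of the score (SE 0.017, n = 119, edgeR adjusted p = 3.81e-63), from a median level of 53.8 CPM. MCAM, the adhesion molecule CD146 (chromosome 11, 119308529 to 119317130), rose by 0.56 (SE 0.018, adjusted p = 1.99e-57), and PPP1R14A, an inhibitor of myosin phosphatase in smooth muscle (chromosome 19, 38251237 to 38256374), by 0.54 (SE 0.017, adjusted p = 1.23e-59). SPEG, a kinase of striated and smooth muscle, rose by 0.48, the muscle heat shock protein HSPB7 by 0.48 and RRAD, a small GTPase that restrains calcium channels, by 0.47. The forkhead factor FOXS1 rose by 0.51, TMEM82 by 0.50, MOB2 by 0.50 and OPN4, the light-sensitive opsin melanopsin, by 0.48.

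Genes of blood cells were among those that fell most. PTPRC, the leukocyte common antigen CD45 (chromosome 1, 198638713 to 198757476), fell by 0.36 per SD (SE 0.025, adjusted p = 2.67e-27) from a median of 40.1 CPM. CYTIP, a cytohesin partner of lymphoid cells, fell by 0.36, the selectin ligand SELPLG by 0.34, the polysialyltransferase ST8SIA4 by 0.33, DENND2D by 0.33 and the blood cell GTPases RAC2 and RHOH by 0.33 and 0.31. LAPTM5, a lysosomal protein of blood cells, fell by 0.32, the leukocyte formin FMNL1 by 0.32 and the homeobox gene PBX4 by 0.31. When all 3 scores were fitted in 1 model RAC2 had -0.034 (adjusted p = 0.224) and LAPTM5 -0.019 (adjusted p = 0.510), and the other falls kept their calls with smaller slopes, from -0.11 for FMNL1 to -0.20 for DENND2D.

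Of the fixed lists, extracellular matrix genes rose most broadly, with 15 of 16 up and none down, among them COL1A1 by 0.35 and elastin, ELN, by 0.35 (camera adjusted p = 1.55e-07, and adjusted p = 0.0504 with an estimated correlation). Pericyte genes rose, 6 of 8 up and none down, with PDGFRB and HIGD1B both by 0.37 (adjusted p = 6.39e-05, and 0.00112 with an estimated correlation). Modulated smooth muscle genes rose, 8 up and 1 down of 11, with TNFRSF11B up by 0.28, LTBP2 by 0.23 and COMP down by 0.12 (adjusted p = 0.00114, and adjusted p = 0.0504 with an estimated correlation). TGF-beta genes rose, 9 up and 1 down of 14, with CCN2 by 0.31, LTBP1 by 0.25 and SMAD2 down by 0.098 (adjusted p = 0.00607, and adjusted p = 0.0826 with an estimated correlation). Genes near coronary artery disease loci rose as a list, with 23 up and 10 down of 41 (23 up and 11 down adjusted over the list alone), COL4A2 and SORT1 up by 0.29 and 0.29 and LPL and KCNK5 down by 0.23 and 0.18 (adjusted p = 0.00111, and adjusted p = 0.0570 with an estimated correlation).

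Immune and lipid lists fell along the contractile score. All 13 T and NK cell genes fell, with IL7R by 0.27 and CD2 by 0.26 (adjusted p = 0.000103, and adjusted p = 0.147 with an estimated correlation), and 13 of 14 macrophage genes, with TYROBP by 0.31 and C1QA by 0.28 (adjusted p = 0.000150, and adjusted p = 0.264 with an estimated correlation). All 10 B and plasma cell genes fell, with TNFRSF17 by 0.36 (adjusted p = 0.00111, and adjusted p = 0.108 with an estimated correlation). Of 15 lipid handling genes 12 fell, led by the fatty acid carrier FABP5 by 0.35 and the scavenger receptor CD36 by 0.30, and NPC2 rose by 0.032 (adjusted p = 0.00111, and adjusted p = 0.143 with an estimated correlation). Of 15 inflammatory genes 11 fell, with IL1B and ICAM1 by 0.27 and 0.27 (adjusted p = 0.00114, and adjusted p = 0.127 with an estimated correlation). Of 8 MHC class II genes 6 fell, with HLA-DRA and HLA-DQA1 both by 0.28 (adjusted p = 0.0337, and adjusted p = 0.497 with an estimated correlation). The interferon list did not pass (adjusted p = 0.0583), with 8 of 12 genes down, MX2 by 0.28, and ISG15 up by 0.057.

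In all, 5026 genes rose and 6372 fell along the contractile score, 65.4% of 17430 tested. Counts adjusted over the list alone were those given except for the coronary artery disease list and, among lists that did not pass, cardiomyocyte genes (4 down in place of 3). The pericyte list alone kept its call with an estimated correlation. Of the 46 list members named along this score 39 kept their calls in the model with all 3 scores and 7 lost them. Endothelial, fibroblast, neuron and oxidative phosphorylation lists, none past the test, had a median, mean and test direction that differed in sign.

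Along the macrophage score, genes of myeloid cells and of leukocytes at large rose and mural cell genes fell. LAPTM5 (chromosome 1, 30732469 to 30757774) rose by 0.46 log2 units per SD of the score (SE 0.020, n = 119, edgeR adjusted p = 1.44e-44) from a median of 61.2 CPM. SIGLEC9, a sialic acid receptor of myeloid cells (chromosome 19, 51119778 to 51136263), rose by 0.44 (SE 0.016, adjusted p = 2.23e-51), RAC2 by 0.44 and LAIR1, an inhibitory receptor for collagen, by 0.42. SELPLG rose by 0.42, THEMIS2 by 0.40, CYTIP by 0.40, the cytohesin CYTH4 by 0.40, PTPRC by 0.39 and ABI3 by 0.38. TINAGL1 fell by 0.33 (SE 0.046, adjusted p = 6.19e-10), PPP1R14A, FOXS1 and MCAM each by 0.32, and the elastic fibre protein MFAP4 and HSPB7 each by 0.31. With the 3 scores in 1 model these 6 falls were lost, with 0.0067 for TINAGL1 (adjusted p = 0.866), 0.018 for PPP1R14A (0.628), -0.0087 for FOXS1 (0.862), 0.048 for MCAM (0.188), -0.032 for MFAP4 (0.499) and -0.031 for HSPB7 (0.388), while the rises named above kept their calls with smaller slopes, from 0.16 for PTPRC to 0.42 for SIGLEC9.

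Some of the larger falls in this comparison depended on a few samples. EEF1A1, a translation elongation factor, fell by 0.40 (SE 0.15, adjusted p = 0.0201) and FHL5, a LIM domain cofactor of muscle at a coronary artery disease locus, by 0.34 (SE 0.094, adjusted p = 0.00112). Without 17 samples with high counts at EEF1A1, FHL5 or TIE1, EEF1A1 had 0.0088 (adjusted p = 0.869) and FHL5 -0.17 (SE 0.039, adjusted p = 0.000102). In the model with all 3 scores EEF1A1 had -0.20 (adjusted p = 0.480) and FHL5 0.0041 (adjusted p = 0.984). CDX1, an intestinal homeobox gene that lies beside PDGFRB, fell by 0.33, but by 0.024 in its gene-end count.

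Lipid handling genes rose along the macrophage score, with 12 of 14 up and none down, led by FABP5 by 0.39 and the apolipoprotein APOC1 by 0.25 (camera adjusted p = 4.69e-06, and 0.00522 with an estimated correlation). All 8 MHC class II genes rose, HLA-DQA1 by 0.43 and HLA-DRA by 0.36 (adjusted p = 4.69e-06, and adjusted p = 0.0665 with an estimated correlation). All 13 T and NK cell genes rose, with NKG7 by 0.33 and CD3E by 0.32 (adjusted p = 1.45e-06, and adjusted p = 0.0722 with an estimated correlation), as did 9 of 10 B and plasma cell genes, with MZB1 by 0.32 (adjusted p = 0.00222, and adjusted p = 0.181 with an estimated correlation). Of 15 inflammatory genes 11 rose, with the chemokine CCL3 by 0.42 and TNF by 0.37, while CCL2 and IL6 fell by 0.084 and 0.095 (adjusted p = 0.000111, and adjusted p = 0.0722 with an estimated correlation). Interferon response genes rose, 8 of 12 with none down, MX2 by 0.29 and OAS2 by 0.22 (adjusted p = 0.00222, and adjusted p = 0.0888 with an estimated correlation).

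All 14 contractile genes fell along the macrophage score, LMOD1 and CNN1 both by 0.28 (adjusted p = 1.22e-07, and adjusted p = 0.161 with an estimated correlation). Of 16 matrix genes 15 fell, the collagen cross-linking enzyme LOX by 0.32 and COL1A1 by 0.29 (adjusted p = 1.22e-07, and adjusted p = 0.0722 with an estimated correlation). Pericyte genes fell, 6 of 8 (7 adjusted over the list alone), with HIGD1B by 0.27 and KCNJ8 by 0.25 (adjusted p = 0.000630, and adjusted p = 0.0722 with an estimated correlation). Modulated smooth muscle genes fell, 8 of 11 with COMP up by 0.088, and with TCF21 and SOX9 down by 0.23 and 0.22 (adjusted p = 0.00291, and adjusted p = 0.0888 with an estimated correlation). Osteochondrogenic genes fell, 8 of 11, BMP4 by 0.30, while osteopontin, SPP1, and RUNX2 rose by 0.17 and 0.078 (adjusted p = 0.0252, and adjusted p = 0.0888 with an estimated correlation). Fibroblast genes fell, 6 of 11, COL1A2 by 0.24, with PI16 up by 0.11 (adjusted p = 0.0299, and adjusted p = 0.292 with an estimated correlation), and TGF-beta genes, 8 of 14 with CCN2 by 0.28, while TGFB1 and TGFBR2 rose by 0.14 and 0.090 (adjusted p = 0.0397, and adjusted p = 0.280 with an estimated correlation). Genes near coronary artery disease loci did not pass as a list (adjusted p = 0.0900), with 12 up, led by LPL by 0.24 and SH2B3 by 0.21, and 22 down of 42.

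In all, 4833 genes rose and 4375 fell along the macrophage score, 52.8% of 17430 tested. With the 3 scores in 1 model the counts were 3124 and 2692, and of the 35 list members named along this score 24 kept their calls, 10 lost them and LMOD1 changed sign (0.026, adjusted p = 0.283). Adjusted over the list alone, endothelial genes gave 4 up in place of 2 and housekeeping genes 1 down in place of 2, and the other lists gave the counts above. Hepatocyte and housekeeping lists, neither past the test, had a median, mean and test direction that differed in sign.

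Along the T and NK cell score, leukocyte genes rose and smooth muscle genes fell. The slopes per SD were larger with depth and gene-end share held fixed. The SD is that of the score itself, which had r = -0.825 with the gene-end share, so slope sizes do not rank the scores. RAC2 (chromosome 22, 37225270 to 37244269) rose by 0.70 log2 units per SD (SE 0.036, n = 119, edgeR adjusted p = 6.45e-37) from a median of 36.5 CPM. LAPTM5 rose by 0.68, CYTIP by 0.67, SELPLG by 0.65, PTPRC by 0.63, TYROBP, the signalling adaptor of NK and myeloid cells, by 0.61, FMNL1 by 0.60, ST8SIA4 by 0.59, LAIR1 by 0.58 and RHOH by 0.58. MCAM fell by 0.62 (SE 0.073, adjusted p = 4.13e-13), FOXS1 by 0.61, TINAGL1 by 0.61, PPP1R14A by 0.60, MFAP4 by 0.57, the Notch target HEYL by 0.57 and MOB2 by 0.56. With the 3 scores in 1 model these falls were lost, with -0.015 for MCAM (adjusted p = 0.906), -0.039 for FOXS1 (0.759), 0.075 for TINAGL1 (0.348), 0.0093 for PPP1R14A (0.942), -0.082 for MFAP4 (0.477), -0.14 for HEYL (0.123) and -0.00019 for MOB2 (0.999), and so was the rise of TYROBP, at 0.068 (0.376). The other rises kept their calls with slopes from 0.18 for ST8SIA4 to 0.39 for RHOH. Without covariates RAC2 rose by 0.39, LAPTM5 by 0.34 and TYROBP by 0.24, and MCAM fell by 0.49. Along the macrophage score without covariates RAC2 and LAPTM5 each rose by 0.45, and MCAM fell by 0.41. FHL5 fell by 0.73 (SE 0.14, adjusted p = 1.85e-06) and EEF1A1 by 0.65 (SE 0.22, adjusted p = 0.00712). Without the 17 samples with high counts, EEF1A1 had 0.015 (adjusted p = 0.848) and FHL5 -0.33 (SE 0.062, adjusted p = 2.93e-06). In the model with all 3 scores EEF1A1 had -0.82 but lost its call (adjusted p = 0.129), and FHL5 had -0.87 (adjusted p = 0.00418). Without covariates both lost theirs, with 0.0035 for FHL5 (adjusted p = 0.972) and 0.020 for EEF1A1 (adjusted p = 0.891).

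All 14 macrophage genes rose along this score, TYROBP by 0.61 and C1QA by 0.55 (camera adjusted p = 3.09e-08, and adjusted p = 0.0588 with an estimated correlation). All 10 B and plasma cell genes rose, MZB1 by 0.59 and MS4A1 by 0.55 (adjusted p = 2.38e-05, and 0.0247 with an estimated correlation). Lipid handling genes rose, 12 of 15, FABP5 by 0.63 and APOC1 by 0.41, with NPC2 down by 0.055 (adjusted p = 3.95e-05, and 0.0408 with an estimated correlation). All 8 MHC class II genes rose, HLA-DQA1 by 0.57 and HLA-DRA by 0.50 (adjusted p = 0.000257, and adjusted p = 0.122 with an estimated correlation). Inflammatory genes rose, 11 of 15, CCL3 by 0.61 and CCL4 by 0.57, with IL6 and CCL2 down by 0.13 and 0.16 (adjusted p = 0.000315, and adjusted p = 0.105 with an estimated correlation), and interferon genes, 8 of 12, MX2 by 0.46 and OAS2 by 0.34 (adjusted p = 0.0113, and adjusted p = 0.187 with an estimated correlation).

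Of 16 matrix genes 15 fell along the T and NK cell score, COL1A1 by 0.53 and LOX by 0.50 (adjusted p = 1.97e-10, and 0.0140 with an estimated correlation). All 14 contractile genes fell, LMOD1 by 0.54 and MYL9 by 0.53 (adjusted p = 2.82e-10, and adjusted p = 0.0963 with an estimated correlation). Modulated smooth muscle genes fell, 8 of 11 with none up, SOX9 by 0.42 and TCF21 by 0.37 (adjusted p = 0.000172, and 0.0140 with an estimated correlation), and pericyte genes, 7 of 8, PDGFRB by 0.48 and HIGD1B by 0.45 (adjusted p = 0.000278, and 0.0408 with an estimated correlation). Genes near coronary artery disease loci fell as a list, 24 down, LMOD1 by 0.54 among them, and 11 up of 42, LPL by 0.37 and APOE by 0.31 (adjusted p = 0.00581, and adjusted p = 0.169 with an estimated correlation). Fibroblast genes fell, 6 of 11, COL1A2 by 0.44, with PI16 up by 0.17 (adjusted p = 0.0113, and adjusted p = 0.239 with an estimated correlation), but without covariates the list changed direction (adjusted p = 0.583). TGF-beta genes fell, 9 of 14, CCN2 by 0.47 and LTBP1 by 0.36, with TGFB1 up by 0.17 among 3 that rose (adjusted p = 0.0113, and adjusted p = 0.142 with an estimated correlation). Without covariates TGFB1 had -0.014 (adjusted p = 0.51). Osteochondrogenic genes fell, 8 of 11, BMP4 by 0.53, with SPP1 and RUNX2 up by 0.29 and 0.12 (adjusted p = 0.0351, and adjusted p = 0.142 with an estimated correlation), and this list, like the fibroblast list, changed direction without covariates (adjusted p = 0.75).

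In all, 5308 genes rose and 4549 fell along the T and NK cell score, 56.5% of 17438 tested, and for every list the counts adjusted over the list alone were those over all genes. Without the covariates 7270 rose and 8135 fell, and 1915 genes past both tests had opposite signs. With the 3 scores in 1 model 1178 rose and 724 fell. Of the 41 list members named along this score 16 then kept their calls, 20 lost them and 5 changed sign, among them LMOD1 at 0.0087 (adjusted p = 0.921), HIGD1B at 0.054 (0.728), C1QA at -0.082 (0.376) and PI16 at -0.0057 (0.966). Cardiomyocyte, hepatocyte, hypoxia, oxidative phosphorylation and housekeeping lists, none past the test, had a median, mean and test direction that differed in sign.

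**Figure D3:**
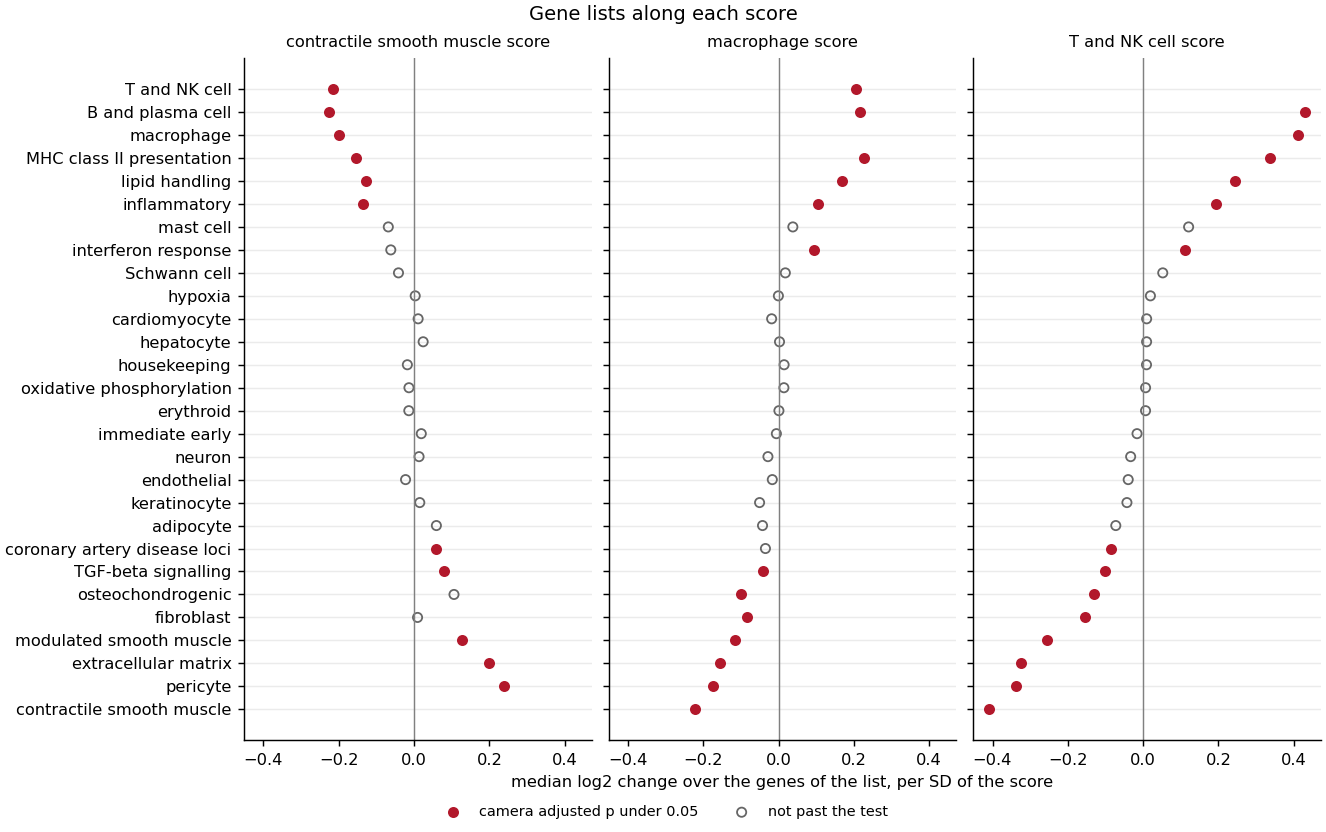
Each point is a gene list, placed by its median log2 change per SD of the contractile smooth muscle, macrophage and T and NK cell scores in 3 panels, filled where the camera adjusted p is under 0.05. Contractile genes have a median of -0.22 along the macrophage score and -0.41 along the T and NK cell score, and extracellular matrix genes 0.20, -0.16 and -0.32 along the 3 scores.

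The macrophage and T and NK cell scores picked out largely the same genes. Of 17416 genes tested on both, 4298 rose and 3901 fell with both, none went opposite ways, and lists drawn independently would share 1463 and 1142. Across genes, which are not independent replicates, the slopes had r = 0.969. Against the contractile score, 3477 genes that rose with it fell with the macrophage score and 3811 went the other way, against 1257 and 1764 for independent lists. For the T and NK cell score the numbers were 3940 and 4502, against 1307 and 1937. The scores themselves correlate, with a partial r of 0.747 for macrophage and T and NK cell. For the contractile score it was -0.618 with macrophage and -0.697 with T and NK cell. Slopes on such scores are bound to overlap or oppose, so independent lists are only a reference. The slopes also come from the same 119 samples, so part of the overlap can come from shared chance deviations.

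Many of the most variable genes across arteries followed the contractile smooth muscle score, with a few exceptions. Their r with it ran from 0.869 for BCAM to 0.949 for IL17B, and was 0.964 for MYH11, a gene of that score. TINAGL1, MCAM and PPP1R14A had biological coefficients of variation of 0.381, 0.376 and 0.364, against a median of 0.105 over tested genes. FOXS1 had 0.353, MOB2 0.343, the cytokine IL17B 0.340, TMEM82 0.338, the laminin receptor BCAM 0.332, HSPB7 0.329 and MYH11 0.329. For IL17B, with 6 linked peaks, the gene-end count gave no value. Whether its linked peaks serve IL17B or a neighbouring gene was not tested. ZDHHC11B, which has a close copy nearby so that its reads are uncertain, had 0.329, and its r with the contractile score was -0.261. The contractile list had a median of 0.246, the B and plasma cell list 0.228, the pericyte list 0.224, the macrophage list 0.218, the T and NK cell list 0.216 and the fibroblast list 0.214, with percentiles of 99.9 for B and plasma cell and 100 for the others among random lists of matched level. Cardiomyocyte genes (0.126, percentile 39.7) and oxidative phosphorylation genes (0.0852, percentile 15) did not stand out.

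The other exceptions lay above these. EEF1A1 had a coefficient of 0.893, FHL5 of 0.612 and the endothelial receptor TIE1 of 0.595. EEF1A1 has processed copies elsewhere in the genome, and how reads shared with them were counted is not given in the sources used here. EEF1A1 (chromosome 6, 73515750 to 73521032) reached 22.9 times its median of 72.9 CPM in sample 99, TIE1 (chromosome 1, 43300982 to 43323108) 20.1 times and FHL5 (chromosome 6, 96562574 to 96618626) 17.9 times in the same sample. No other gene reported here with a median of at least 20 CPM exceeded 3.62 times its median in any sample. At EEF1A1 the excess sat in 2 of 4 linked peaks. At FHL5 6 of 14 linked peaks exceeded 10 times their median in sample 99 and 7 stayed within 2-fold.

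**Figure D4:**
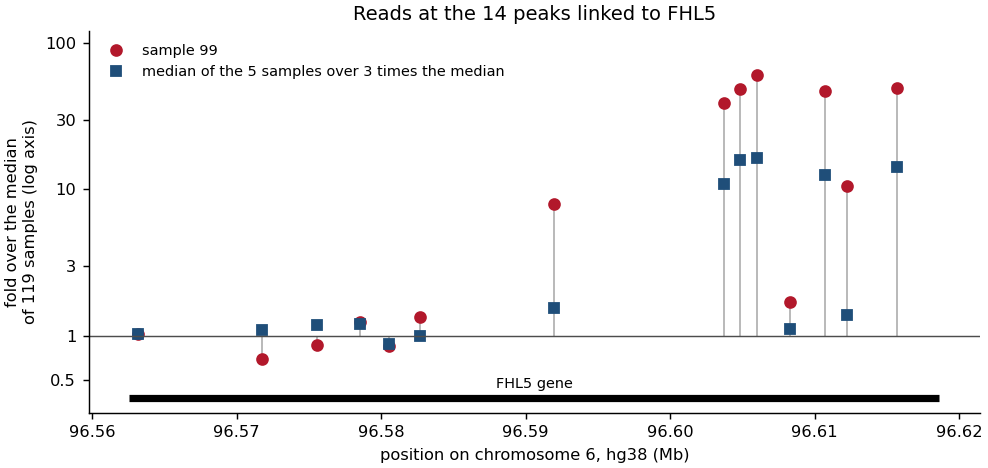
Reads at the 14 peaks linked to FHL5 along chromosome 6 (hg38, Mb), as fold over the median of 119 samples (log axis), for sample 99 in circles and as the median of the 5 samples over 3 times the gene's median in squares. Of the 14 peaks 6 exceed 10-fold in sample 99 and 7 lie within 2-fold, including 1 between raised peaks.

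The largest axis of variation between samples followed the gene-end share and cell type scores, those of cells from outside the artery among them. A smaller axis also set smooth muscle against macrophages. The leading component held 33.1% of the variance of 167011 peaks and had r = 0.901 and rho = 0.909 with the gene-end share (r = 0.895 without 2 samples), and r = -0.912 and rho = -0.865 with the T and NK cell score (r = -0.894 without 2 samples). Its largest r was that with the mast cell score (r = -0.915, rho = -0.888, r = -0.898 without 2 samples), and it had r = 0.586 with the contractile and -0.543 with the macrophage score. It also had r = -0.858 with the neuron, -0.748 with the hepatocyte and -0.668 with the keratinocyte score, cell types from outside the artery. The T and NK cell and mast cell scores had r = -0.825 and -0.920 with the gene-end share itself. Cell content and signal against background thus cannot be told apart on this component. The second component held 9.15% and rose with the modulated smooth muscle score (r = 0.811, rho = 0.751, r = 0.754 without 2 samples) and the contractile score (r = 0.70, rho = 0.670, r = 0.642 without 2 samples). It fell with the macrophage score (r = -0.674, rho = -0.690, r = -0.681 without 2 samples). The component after it held 5.31% and fell with the fibroblast score (r = -0.565, rho = -0.616, r = -0.550 without 2 samples). Each r and rho of a component given above had a permutation p of 1e-05 and, over the 45 relations, an adjusted p of 1.87e-05. With the 5000 most variable peaks alone, the second component had r = -0.169 (permutation p = 0.0653) with the contractile and 0.092 (p = 0.315) with the modulated smooth muscle score, so both relations were lost, and the component after it had r = 0.638 with the fibroblast score, the opposite sign.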

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

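The tests of signal against background for the opposed scores and all tests of the high counts at 3 genes were chosen only after those results were seen, and the other tests of this part were planned. Peaks on unplaced sequence, which no comparison uses, held reads in every sample. These 261 peaks took a median of 0.174% of reads in peaks, with a range of 0.0481% to 0.295% and 6161 to 30464 reads per sample. The limit that a count of 0 would allow, 3 counts per library, is at most 0.000092%. Whether these reads come from repeats, from sequence missing in the assembled chromosomes or from other sources was not tested.

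Contractile smooth muscle and macrophage scores went in opposite directions over the 119 samples. If smooth muscle regions only took reads from all other regions, the contractile score would also oppose the hepatocyte, neuron and keratinocyte lists, but its partial r with their mean was 0.345 (95% interval 0.175 to 0.496). Differences in signal against background between libraries, as measured by depth, gene-end share and that mean, left a partial r of -0.548 (95% interval -0.664 to -0.407), wholly below the bound of -0.3. A change in the mix of cells, with fewer smooth muscle nuclei where macrophages and lymphocytes are many, may be the source, but the labels give no group and no biological explanation was tested. Background that those 3 measures miss stays open. The strongest peaks of the hepatocyte, neuron and keratinocyte genes lay near the intergenic level, with medians of 1.69, 1.71 and 1.12-fold. Background shared with the many linked peaks of contractile genes could therefore hide a loss of reads. The partial r of 0.345 thus does not exclude such a loss.

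The numbers of genes along the scores were set against 100 random orders of each score and 100 random lists of matched size and level, by limma. With the samples in random order, 0 of 100 gave as many genes for the contractile score (11212 observed, 554 the highest other), 0 for the macrophage score (9045, against 198) and 0 for the T and NK cell score (9571, against 2). Each score was made from these same counts, so scores of arbitrary lists can beat a random order too. This comparison therefore says nothing on the markers. Random lists gave as many genes in 0 of 100 cases for the contractile score (highest 10994, median 7096), in 4 for the T and NK cell score (highest 10145, median 3886) and in 5 for the macrophage score (highest 9578). As 5 of 100 arbitrary lists reached the macrophage count, its size alone is not specific to macrophages. What is specific to each score was not tested, nor was any biological explanation.

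EEF1A1, FHL5 and TIE1 had very high counts in a few samples, 17 of 119 with over 3 times the median at any of them. The highest fold of any other gene reported here was 3.62, but that search was limited to genes up to 10-fold. It therefore cannot decide on depth or normalization. Over the 14 samples high at EEF1A1, 2 of its peaks had median folds of 1.00 and 1.08, which argues against a scale of the whole library. More copies or opening of the whole FHL5 region is argued against by a peak between raised peaks with a median fold of 1.11. At TIE1 8 of 9 peaks were raised, so the whole region is not excluded there. Of 8 samples over 3 times the median at FHL5 or TIE1, 5 were among the 14 over it at EEF1A1 (Fisher's exact test, p = 0.00050), with all 5 of those over it at FHL5 (p = 1.1e-05) but 1 of 4 at TIE1 (p = 0.398), which at FHL5 and EEF1A1 is in line with DNA of another source that carries parts of them, such as expression constructs, as a hypothesis, and leaves TIE1 open. Many of the 17 samples had close sample numbers. Samples 98 and 100, next to sample 99, had 11.7 and 4.83 times the median at FHL5. At TIE1, samples with 5.28 and 6.69 times the median were also close to sample 99 in number. Sample 33, with 6.44 times at TIE1, and samples 17, 18 and 35, high at EEF1A1, were not. The labels give no batch or date, so whether samples close in number were handled together was not tested. At EEF1A1 the 2 raised peaks lay at 1 gene end, and 1 of them reached past it. The peak at the other end had folds of 0.83 to 1.47 over the 14 samples. Copies of the whole transcript would raise both ends, so this argues against reads shared with such copies there. Partial copies, and processed copies of FHL5 and TIE1, stay open, because exons are not annotated here. No biological explanation was tested.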

How the results depend on the processing

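The strongest peak, the outside cell type covariate, the samples left out for the second component and the 17 samples left out for high counts were chosen after the data were seen, and the other alternatives were planned. Unless a construction is named, the cause was not tested. Of 1439 repeats of a named gene's slope 1348 kept direction and side of the threshold, 73 lost the threshold and 18 changed sign. Of 405 repeats of list tests 309 kept both, 50 lost and 13 gained the threshold and 33 changed direction, most of them for lists that passed under neither setting. Of 77 repeats of r between scores 60 kept both, 7 gained the threshold and 10 changed sign. Of 84 repeats of list levels 39 moved by less than 1 SD between samples and 45 by more. Of 128 repeats of main counts and values 24 moved, 1 was weaker, 2 changed sign and the others held. The DESeq2 test gave 4829 up and 6683 down for the contractile score, 4916 and 4383 for macrophage and 5485 and 4498 for T and NK cell.

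With gene-end counts, 4 lists in place of 8 lay above the 95th percentile of matched lists and 14 in place of 9 below the 5th. With counts per kb and with the strongest peak, 3 and 4 lay above. The contractile list stood at 18.2, 33.4 and 24.6 under these 3 settings. Contractile and cardiomyocyte scores went from r = -0.043 to 0.593 with gene-end counts, and contractile and fibroblast scores to 0.054. Of the 15 most variable genes 7 were shared with that count. Lists past no test that changed direction with it were endothelial (adjusted p = 0.922) and erythroid (0.893) along the contractile score, erythroid (0.539), immediate early (0.955) and oxidative phosphorylation (0.999) along macrophage, and erythroid (0.620) and immediate early (0.993) along T and NK cell.

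With depth and gene-end share partialled out, 18 pairs were positive and 19 negative, and r was 0.477 for contractile and cardiomyocyte, 0.185 for contractile and fibroblast and -0.058 for endothelial and cardiomyocyte scores. With the outside cell types partialled out as well, the numbers were 15 and 17, 0.373, 0.034 and -0.132. With medians of z scores fibroblast and macrophage scores had r = 0.051, and with DESeq2 size factors contractile and fibroblast scores had r = 0.0015.

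With the 3 scores in 1 model, where each score is fitted beside scores it correlates with, macrophage counts were 3124 up and 2692 down and T and NK cell counts 1178 and 724. There the macrophage slopes were 0.0041 for FHL5, 0.0067 for TINAGL1, 0.018 for PPP1R14A, 0.048 for MCAM and 0.026 for LMOD1. The T and NK cell slopes were 0.075 for TINAGL1, 0.0093 for PPP1R14A, 0.0087 for LMOD1, 0.054 for HIGD1B, 0.084 for CA9, -0.082 for C1QA and -0.0057 for PI16.

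Without covariates 8135 genes fell along the T and NK cell score, and the median coefficient of variation was 0.163. Slopes along that score were then 0.0035 for FHL5, 0.020 for EEF1A1, 0.10 for CDH19 and -0.014 for TGFB1. In that setting 3 lists fell along the T and NK cell score, and fibroblast (adjusted p = 0.583), osteochondrogenic (0.75), endothelial (0.0250), cardiomyocyte (0.0496), neuron (0.0238), adipocyte (0.523), hepatocyte (0.109), keratinocyte (0.514) and housekeeping (0.0526) lists changed direction. Along the contractile score the endothelial (0.281), cardiomyocyte (0.889), neuron (0.402), keratinocyte (0.882), housekeeping (0.889) and oxidative phosphorylation (0.42) lists did so. Along the macrophage score these were the endothelial (0.124), cardiomyocyte (0.590), hepatocyte (0.782), neuron (0.360), housekeeping (0.513) and oxidative phosphorylation (0.124) lists.

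Without samples 26 and 86 the endothelial (adjusted p = 0.994) and keratinocyte (0.950) lists changed direction along the contractile score. With the outside cell type covariate the neuron (0.917) and keratinocyte (0.723) lists did so along that score, and oxidative phosphorylation (0.967) along macrophage.

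Without the 17 samples, EEF1A1 had slopes of 0.0088 along the macrophage score and 0.015 along the T and NK cell score. With an estimated correlation camera called 1 list up and 0 down for the contractile score in place of 5 and 6, 1 and 0 for macrophage in place of 6 and 7, and 2 and 3 for T and NK cell in place of 6 and 8. With the 5000 most variable peaks the leading component held 65.2% and the second 5.74% of the variance. The second then had r = -0.169 with the contractile and 0.092 with the modulated smooth muscle score, and the third r = 0.638 with the fibroblast score, where each component took the sign that correlates positively with its counterpart over all peaks.

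Motif windows and backgrounds and the overlap for recurrent peaks were not run, since no genome sequence and no peak calls per sample were used here, and promoter windows were replaced by windows at both gene ends. No paired analysis was possible because the samples carry no groups or shared replicate numbers. Slopes of 0.05 per SD were recovered in 8% of simulated genes on the T and NK cell score, where few genes were changed. In the data 56.5% of tested genes passed along that score, which loosens the adjusted threshold. The simulated share therefore does not give the share of such effects missed here.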

Other observations

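The samples singled out in this part were chosen only after their values were seen, and the list results were planned. Lists that did not pass as a whole held members that moved strongly. Of all tested genes 65.4%, 52.8% and 56.5% passed along the contractile, macrophage and T and NK cell scores. Members past the test in both directions therefore do not by themselves set a list apart. Along the contractile score, the fat genes CIDEA and PLIN1, which coat lipid droplets, rose by 0.33 and 0.23 log2 units per SD while PPARG and LIPE fell by 0.24 and 0.12 (adipocyte list, 5 up and 3 down of 9, camera adjusted p = 0.539). Of endothelial genes KDR and ERG rose by 0.24 and 0.15, and ROBO4 and PECAM1 fell by 0.18 and 0.16 (3 up and 5 down of 12, adjusted p = 0.953). Of fibroblast genes COL1A1 and PDGFRA rose by 0.35 and 0.22 and MFAP5 and C7 fell by 0.31 and 0.18 (5 up and 5 down of 11, adjusted p = 0.590). BMP4 rose by 0.28 and SPP1 fell by 0.19 among osteochondrogenic genes (7 up and 3 down of 11, adjusted p = 0.322). APOB, a hepatocyte marker, rose by 0.30 along this score and fell by 0.25 and 0.43 along the macrophage and T and NK cell scores, although its list did not pass along any of the 3.

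Schwann cell markers also split. S100B, which dendritic cells express too, rose by 0.43 along the macrophage score and 0.54 along the T and NK cell score, while CDH19 fell by 0.15 and 0.20 (adjusted p of the list 0.237 and 0.358). Without covariates CDH19 had -0.044 along the macrophage score (adjusted p = 0.265) and rose by 0.10 along the T and NK cell score (adjusted p = 0.00258). Mast cell genes had 4 of 6 members up along the T and NK cell score, HDC by 0.38 and HPGDS by 0.26, with GATA2 down by 0.23 (adjusted p = 0.172). KLF1 of the erythroid list rose by 0.36 along the T and NK cell score (2 up of 6, adjusted p = 0.550). CA9 and EGLN3 of the hypoxia list rose by 0.33 and 0.20 along the contractile score and fell by 0.25 and 0.28 along the T and NK cell score (5 up and 5 down, and 3 up and 4 down, of 13, adjusted p = 0.526 and 0.641). With the 3 scores in 1 model CA9 had 0.084 along the T and NK cell score (adjusted p = 0.390). Immediate early genes moved little, with MAFF and EGR3 up by 0.14 and 0.13 along the contractile score and 5 of 15 past the test (adjusted p = 0.322). Neuron, keratinocyte, cardiomyocyte, housekeeping and oxidative phosphorylation lists did not pass along any of the 3 scores with the covariates in the model. Without covariates the neuron (adjusted p = 0.0238) and cardiomyocyte (adjusted p = 0.0496) lists passed along the T and NK cell score, with changed direction.

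Samples 26 and 86 stood apart at the low end of the second component. With depth and gene-end share regressed out, sample 86 had the lowest contractile, modulated smooth muscle and extracellular matrix scores, at -3.74, -3.79 and -3.92 SD, and the highest T and NK cell and B and plasma cell scores, at 4.33 and 4.39 SD. Its MYH11 level was 62.4 CPM against a median of 153 CPM, and its CNN1 level 11.4 against 36 CPM. Sample 26 had the highest macrophage and lipid handling scores, at 2.49 and 3.82 SD, a T and NK cell score of 3.58 SD and the lowest TGF-beta and osteochondrogenic scores, at -3.05 and -3.54 SD. It had 73.9 CPM at CD68 against a median of 49.9 CPM and 85 CPM at MYH11. Without both samples 4749 genes rose and 6209 fell along the contractile score, 4496 and 4005 along the macrophage score, and 4935 and 3982 along the T and NK cell score.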
